A study of Mus musculus with 16 samples.

How the data were processed

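Gene expression was measured by RNA sequencing of the hypothalamus of C57BL/6N mice, an inbred laboratory strain, fed on 8 diets. Per the labels, the diets crossed 60% or 20% of energy from fat with 1%, 2.5%, 5% or 20% of energy from protein, and each diet had 2 libraries numbered as replicates. Total RNA was extracted with Trizol, per the labels' protocols. The deposited table holds raw gene counts for 47069 genes in 16 libraries. The authors left these counts unnormalised, and their totals ran from 17731242 to 18511818 per library. The tools named are FastQC, HISAT2 2.1.0, SAMtools 1.2, featureCounts, Subread 5.0 and edgeR with the mouse build GRCm38, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an antisense neighbour cannot be told apart. Because the labels do not say that the libraries of a diet came from separate animals, p-values measure only the spread between these samples, which may be technical.

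The deposited table also gives a length for each gene. That length equalled the whole span of the gene on the genome, introns included, for 85.5% of the 46574 identifiers matched to GENCODE M21, and for 76.6% of the genes tested. A count over such a span can take in reads from introns. Where another gene overlaps the span, reads may be gained or lost, depending on how shared reads were counted. Of 131 genes named for a test, 56 overlap another annotated gene and 16 overlap a coding gene: Plin4, Itgad, Pla2g3, Prg4, Agrp, Oprm1, Cebpb, Dusp1, Ndufb9, Cyp51, Hexa, Cryab, Ermn, Bmp4, Pmch and Mtor. Their counts are uncertain to that extent, as are those of ribosomal protein genes, which have many near-identical copies. Overlaps were taken from the annotated spans, and the counted length of Dusp1, 2930 bases, is far shorter than its annotated span on chromosome 17 (26505590 to 26562128).

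Genes were kept with edgeR's filterByExpr (minimum count 10), which left 16646, and libraries were scaled with TMM factors. The main test was the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05, fitted to all 16 libraries, which share an estimate of the spread. Following the model in the series' design text, expression was fitted on protein, fat and their interaction, and the interaction was dropped for genes whose interaction p was above 0.05. Protein was scaled so that the slope is the log2 change from 20% to 1% protein. A second model took protein as 4 levels, with fat, for the contrasts of protein levels, and another took the 8 diets as separate groups. CPM values are TMM-scaled counts relative to the library total, and log2 CPM used a prior count of 2. Pearson correlations with protein within each fat level used an exact permutation test, two-sided, over the 2520 distinct arrangements of the protein levels among 8 libraries. The replicate numbers were not used as a block in the main models.

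Lists fixed beforehand, 23 of gene functions and 21 of cell types, nuclei and neighbouring tissues, were tested with camera at a preset inter-gene correlation of 0.01 (limma 3.58.1). Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction without comparing them with other genes. The rule for naming genes took the 10 highest and 10 lowest log2 changes past the threshold with a mean of at least 1 CPM for the protein slope, the fat effect and 1% against 20% protein, and the 5 highest and 5 lowest for other contrasts. It added up to 4 members per list past the threshold along the slope and the fat effect, and Agrp, Npy, Pomc, Cartpt, Hcrt, Pmch and Mtor for the slope whether or not they passed. Predicted genes without a proper symbol were counted and not named. The models, lists, naming rule and most alternatives were fixed before the data were examined. The list tests and list members for 1% against 20% protein, with the members' values under the alternatives, the core appetite genes outside the slope, the test of the difference between fat levels, the removal of a gene length trend and the removal of the libraries with cortex markers were added after seeing the data.

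Alternatives were median-ratio scaling, DESeq2 1.42.0, edgeR's likelihood ratio test, other count filters, the replicate number as a block, a surrogate variable (sva 3.50.0), protein on a log2 scale, a term for the start of the diet code, fits on fewer libraries and leaving out each library in turn. The steps were tested on simulated counts. These were drawn independently for each gene, with no library that stands apart and no trend shared between genes. The rates below therefore do not describe calls on real libraries with such structure. For 1% against 20% protein, 73% of 100 genes changed by log2 0.5 and 98% of 100 changed by log2 1 were recovered, with 9 false calls of 180. For the protein slope the shares were 82% and 99%, with 9 false calls of 190. The 2 libraries of each diet differed by more than counting noise, with a chi-square per degree of freedom from 2.94 to 24.3, so neither was a copy of the other. Separate preparations of the same RNA would also differ so, and this does not show that the libraries came from separate animals.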

Results

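The hypothalamus, the brain region that governs food intake and energy balance, was profiled in mice on diets that differed in protein and fat. The study asked how dietary protein changes hypothalamic gene expression at each of 2 fixed fat levels, with food intake and mTOR signalling as its theme. There were 8 diets with 2 libraries each, from 1% to 20% of energy as protein at 60% or 20% of energy as fat. Every protein level was thus covered by 4 libraries and every fat level by 8. Total counts ran from 17731242 to 18511818 per library, and 25554 of 47069 genes had a count in at least 1 library.

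Some libraries stood apart in their RNA makeup. Genes of the mitochondrial genome held 1.54%, 1.61% and 1.78% of the counts in 3 of the 4 libraries at 1% protein, both at 60% fat and replicate 1 at 20% fat. In the other 13 libraries the share ran from 2.19% to 3.20%, and the highest belonged to replicate 2 of 20% fat with 1% protein. In the same 3 libraries longer genes stood lower relative to the mean of all libraries, with a Spearman correlation across genes of -0.295, -0.202 and -0.295 with gene length, against 0.196 in replicate 2 of 20% fat with 1% protein. The other 12 libraries ran from -0.161 to 0.369, and 3 of them lay close to the -0.202: replicate 1 of 20% fat with 5% protein (-0.161), replicate 1 of 60% fat with 5% protein (-0.154) and replicate 1 of 20% fat with 20% protein (-0.112). Markers of cortical and hippocampal neurons averaged log2 0.71 above the mean of all libraries in that replicate 2 and 1.38 in replicate 2 of 20% fat with 2.5% protein, and between -0.38 and 0.009 elsewhere. Slc17a7, a vesicular glutamate transporter of cortical neurons, reached 5074 and 10337 counts in those libraries.

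**Figure D1:**
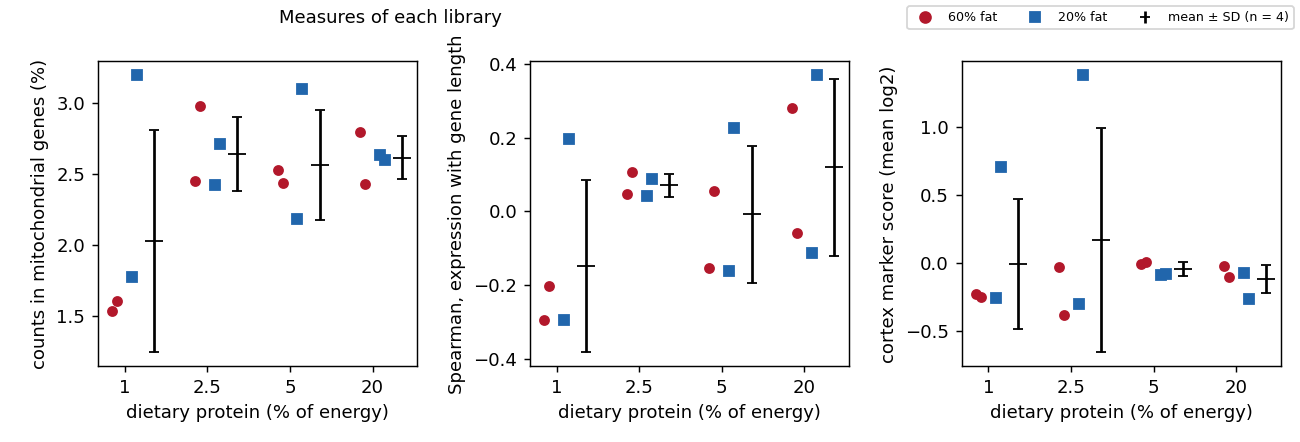
Each point is a library, by dietary protein (% of energy) and fat level, for the percentage of counts in mitochondrial genes, the Spearman correlation of expression with gene length, and the cortex marker score (mean log2 relative to all libraries); black marks are the mean ± SD (n = 4). Of the libraries at 1% protein, 3 lay lowest in mitochondrial share (1.54% to 1.78%), while the 4th had 3.20%.

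Along the fitted slope from 20% to 1% protein, the metallothionein genes rose, although their means at 2.5% lay below those at 5%. Mt2 and Mt1, which encode metal-binding stress proteins, rose by log2 0.74 ± 0.11 (SE) and 0.66 ± 0.11 from 20% to 1% protein, and Wnt6, a secreted signalling protein, changed by -0.96 ± 0.16. Mt2 averaged 82.3 ± 7.95 CPM at 20% protein, 126 ± 6.63 at 5%, 113 ± 13.2 at 2.5% and 151 ± 2.53 at 1% (SD, n = 4 each). Mt2 and Mt1 are neighbours on chromosome 8 (94172664 to 94173568 and 94179082 to 94180327), and Wnt6 lies on chromosome 1 (74771892 to 74785322). These 3 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0216, 0.0396 and 0.0396), and 2435 had an unadjusted p under 0.05. Of 29 alternatives Mt2 failed to pass in 7, Mt1 in 11 and Wnt6 in 15.

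The appetite genes did not pass along this linear slope. Npy, whose peptide stimulates feeding, had a slope of log2 1.67 ± 0.38 (SE), Agrp, made in the same arcuate neurons, 0.45 ± 0.14, and Pomc, the precursor of an appetite-suppressing melanocortin, -1.26 ± 0.30, with adjusted p = 0.145, 0.21 and 0.152 in edgeR's quasi-likelihood test. Cartpt, another satiety peptide, had -0.35 (adjusted p = 0.27), and Hcrt and Pmch, the orexin and melanin-concentrating hormone genes of the lateral hypothalamus, 0.33 (0.332) and 0.08 (0.744). Mtor, the kinase of the mTOR complexes, had -0.0024 (0.983). Of 44 lists, 13 passed camera along the slope, none with an estimated correlation (adjusted p = 0.168 to 0.682), and 5 in fry. Glucocorticoid response genes led them: 2 of 22 rose over all genes, Mt1 and Mt2, and 16 rose adjusted over the list alone, with a median of 0.72 (adjusted p = 0.168 with an estimated correlation). Ribosomal protein, respiratory chain and thalamic lists had positive medians (0.17, 0.13 and 0.43), with no member past the threshold over all genes or adjusted over the list alone. Mural and fibroblast-like (median -0.39; 7 fell and 1 rose adjusted over the list alone), heat shock (-0.23; 5 fell), endothelial (-0.25; 2 fell), reproductive (-0.24; 3 fell), inflammatory (-0.13; 4 fell and 1 rose) and appetite receptor lists (-0.05; 4 fell and 1 rose) lay lower. Interferon (-0.17; 1 fell), cholesterol synthesis (-0.07; 2 fell) and GABA and glutamate lists (-0.11; none) also lay lower, and no member of any of these 9 lists passed over all genes. The inflammatory list's mean was -0.0099.

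The slope's count of 3 genes became 1311 with protein on a log2 scale, 82 with DESeq2, 100 with the likelihood ratio test and 0 with a term for the start of the diet code. It was 0 without either library of 60% fat with 20% protein, replicate 2 of 20% fat with 1% protein or replicate 2 of 20% fat with 20% protein. It was 1 without replicate 2 of 60% fat with 1% protein, replicate 1 of 60% fat with 5% protein or replicate 1 of 20% fat with 20% protein. The value was 5 without replicate 2 of 60% fat with 5% protein or replicate 1 of 20% fat with 5% protein, and 10 without replicate 2 of 60% fat with 2.5% protein.

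**Figure D2:**
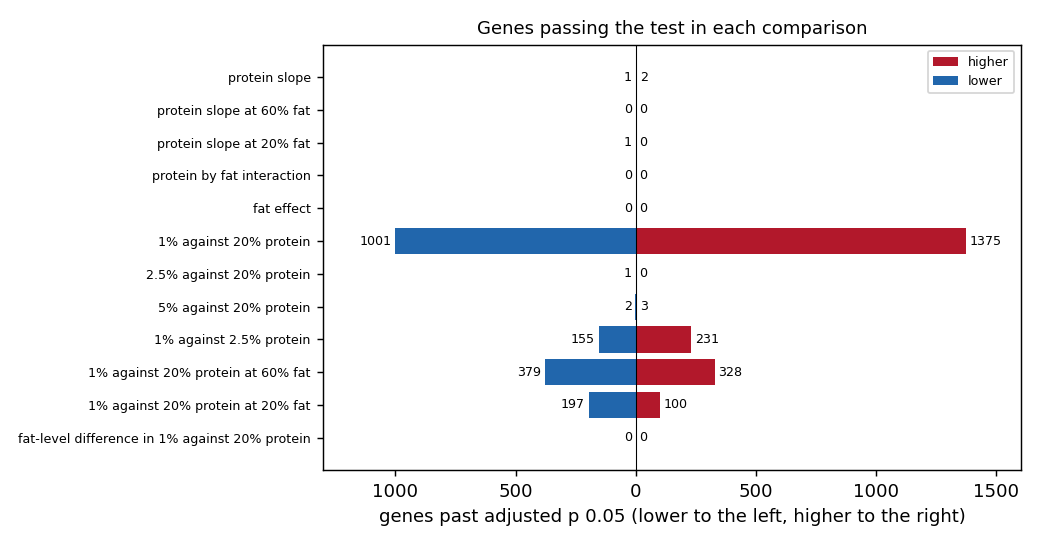
Bars give the genes past an adjusted p of 0.05 (edgeR quasi-likelihood test) in each comparison, higher to the right and lower to the left, on a linear axis of genes. The contrast of 1% against 20% protein had 1375 higher and 1001 lower genes, and the fat effect had none.

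The contrast of the lowest with the highest protein level asked which genes changed at 1% protein over both fat levels. Npy rose 4.50-fold (log2 2.17 ± 0.20 SE), from 17.2 ± 3.57 CPM at 20% protein to 80.3 ± 29.6 at 1% (SD, n = 4 each). Pomc was 3.75-fold lower (log2 -1.91 ± 0.19), at 12.7 ± 1.2 against 47.5 ± 7.56 CPM. Agrp, an antagonist at melanocortin receptors, rose by log2 0.59 ± 0.13, from 4.62 ± 0.584 to 6.94 ± 1.06 CPM. All 4 libraries at 1% protein lay beyond all 4 at 20% for each of these genes (adjusted p = 1.1e-05, 2.67e-05 and 0.0103 in edgeR's quasi-likelihood test). At 2.5% and 5% protein Npy averaged 31.1 and 24.1 CPM, Pomc 25.3 and 37.7, and Agrp 5.52 and 5.37. In GRCm38, Npy (ENSMUSG00000029819) lies on chromosome 6 (49822710 to 49829507), Pomc (ENSMUSG00000020660) on chromosome 12 (3954951 to 3960642) and Agrp (ENSMUSG00000005705) on chromosome 8 (105566698 to 105637393), where its counted span of 70696 bases overlaps 7 other genes, 2 of them coding.

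Among 11 measured orexigenic peptide genes, Npy, Agrp and Qrfp (log2 0.78, adjusted p = 0.0484) rose and 8 did not pass (adjusted over the list alone 3 rose and 1 fell, camera adjusted p = 0.101). The list passed camera without replicate 2 of 20% fat with 1% protein (adjusted p = 0.0377) and without replicate 1 of 20% fat with 20% protein (0.0403). It also passed without the 2 libraries that carried cortex markers (0.0085, 4 rose and 1 fell), while a surrogate variable gave 0.782, with 2 that rose and 2 that fell. In the main fit the orexigenic list did not pass with an estimated correlation. Its median in replicate 2 of 20% fat with 1% protein against 5% protein at that fat level was -0.35, and 0.21 in the contrast without that library. Hcrt was at 0.34 (0.157) and Pmch at 0.00074 (0.998) in edgeR's quasi-likelihood test. Hcrt did not pass in 24 of 26 alternatives, over which its log2 change ran from -0.003 to 0.511. In 3 of 4 libraries at 1% protein Hcrt lay above all at 20%, while replicate 2 of 20% fat had a log2 CPM of 6.663. Of 17 anorexigenic peptide genes, Pomc, Avp (-0.58, vasopressin), Cartpt (-0.44) and Nts (-0.37, neurotensin) fell, Crh (0.33, corticotropin-releasing hormone) rose and 12 did not pass. Adjusted over the list alone 2 rose and 7 fell (camera adjusted p = 0.0295 and adjusted p = 0.448 with an estimated correlation). Qrfp, Avp, Cartpt, Nts and Crh lay close to the threshold and did not pass in 7 to 17 of 26 alternatives each. Of 28 appetite receptor and signalling genes, Ramp3 (0.75), which is also a thalamic marker, and Ntrk2 (0.14) rose, and Socs3 (-0.79), an inhibitor of leptin signalling, Hcrtr2 (-0.56), Htr1b (-0.46), Npy2r (-0.41), Calcr and Stat3 fell (adjusted over the list alone 3 rose and 7 fell, camera adjusted p = 0.246). Of these, Ntrk2 did not pass in 18 of 26 alternatives, Hcrtr2 in 13, Calcr in 11, Stat3 in 8, Htr1b in 6 and Ramp3 in 5. The thalamic list that holds Ramp3 had a median of 0.62, and Prkcd, another of its genes, 1.06. Of 23 reward genes, Oprm1 (-0.51) and Slc18a2 (-0.46) fell and 21 did not pass (adjusted over the list alone 2 fell; 0.246).

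**Figure D3:**
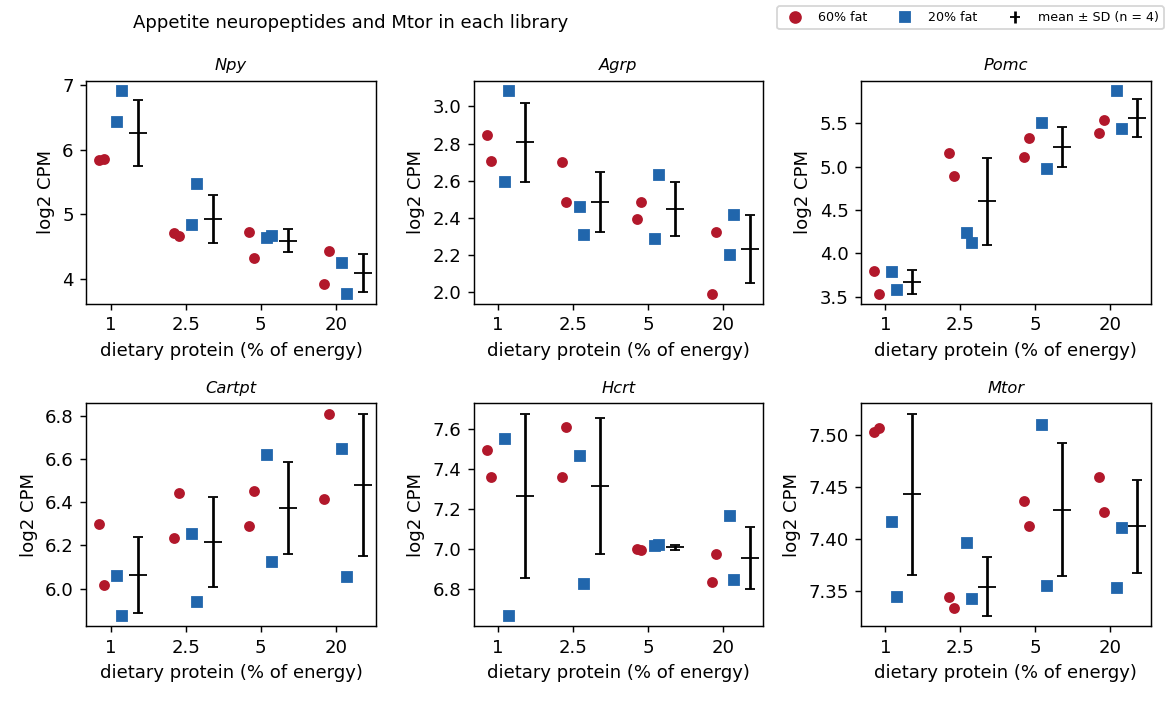
Each point is a library's log2 CPM of Npy, Agrp, Pomc, Cartpt, Hcrt or Mtor by dietary protein (% of energy), circles for 60% fat and squares for 20% fat, with black marks for the mean ± SD (n = 4). All 4 libraries at 1% protein lay above all 4 at 20% for Npy and Agrp and below them for Pomc.

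Glucocorticoid response genes rose together at 1% protein: 19 of 22 measured rose, 1 fell and 2 did not pass (adjusted over the list alone 20 rose and 1 fell, median log2 0.97). Plin4, which coats lipid droplets, rose 4.83-fold (17.4 ± 5.72 to 83.5 ± 23.3 CPM, SD, n = 4 each), Cdkn1a, a cell cycle inhibitor, 4.04-fold (21.7 ± 4.03 to 87.6 ± 30.7), and Ddit4, an inhibitor of mTORC1, 2.15-fold (49.1 ± 2.43 to 106 ± 7.84). Their log2 changes were 2.27 ± 0.32, 2.01 ± 0.24 and 1.10 ± 0.08 (SE and adjusted p = 0.000438, 0.000114 and 1.38e-06 in edgeR's quasi-likelihood test), with all 4 libraries at 1% above all 4 at 20%. Hif3a (1.55), Arrdc2 (1.48), Sult1a1 (1.33), Fkbp5 (1.31), a chaperone of the glucocorticoid receptor, Sgk1 (1.2), Mt2 (0.88) and Mt1 (0.84) rose too, and Nr3c1, the receptor itself, changed by -0.25. Lcn2, an iron-binding protein of inflammation, had 2.60, with 105 counts in replicate 2 of 20% fat with 1% protein and 2 to 15 in each other library, and did not pass in 17 of 25 alternatives. The list passed camera (adjusted p = 4.84e-32 and adjusted p = 0.0655 with an estimated correlation) and fry (0.000663). Its median was 0.94 in replicate 2 of 20% fat with 1% protein set against 5% protein at that fat level, and 0.88 in the contrast without that library. Some of its genes recur in the lists below: Per1 in the clock, Pdk4 in the fatty acid and ketone and Dusp1 in the immediate early list. Lcn2 and Nfkbia recur in the inflammatory list. Their rises there are not separate changes.

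Of 55 genes of the mTOR complexes and their regulators, 7 rose, 1 fell and 47 did not pass (adjusted over the list alone 9 rose and 1 fell, camera adjusted p = 0.0782; fry 0.000663). Without replicate 2 of 20% fat with 1% protein 14 rose and 7 fell, and without the cortex-marker libraries 15 rose and 8 fell, so the list then went both ways. The 7 that rose became 1 without any of the libraries of 60% fat with 1% or 20% protein, and 2 with a surrogate variable. It became 2 to 4 without 8 others: replicate 1 of 20% fat with 1% protein, replicate 1 of 60% fat with 2.5%, replicate 2 of 20% fat with 2.5%, both of 60% fat with 5%, replicate 2 of 20% fat with 5%, and both of 20% fat with 20% protein. The list passed camera with the length offset (adjusted p = 0.0305), but in the main fit it did not pass with an estimated correlation. Ddit4 changed most. Prr5, Tbc1d7, a subunit of the TSC complex, Lamtor1, Sesn1, a stress-induced mTORC1 inhibitor, Sec13 and Akt1 rose by 0.18 to 0.27, and Prr5l fell by 0.34, but these calls were often lost: of 26 alternatives Akt1 did not pass in 18, Sec13 in 17, Prr5 and Tbc1d7 in 14 each, Lamtor1 in 8, Prr5l in 7 and Sesn1 in 6. Mtor was at 0.03 (adjusted p = 0.676, edgeR's quasi-likelihood test). Of 25 mTORC1 effectors, Eif4b (0.32), Maf1 (0.26), Rps6 (0.23) and Atg13 (0.23) rose and 21 did not pass (adjusted over the list alone 8 rose and 1 fell, camera adjusted p = 0.131). Of 45 genes of amino acid deprivation and the ATF4 response, 15 rose, 5 fell and 25 did not pass (adjusted over the list alone 20 rose and 6 fell, camera adjusted p = 0.00247 and adjusted p = 0.39 with an estimated correlation). The 15 became 4 without either library of 60% fat with 1% protein, replicate 1 of 60% fat with 20% protein or replicate 1 of 20% fat with 1% protein. It became 5 without replicate 2 of 20% fat with 20% protein, 8 without replicate 1 of 60% fat with 2.5% or replicate 2 of 60% fat with 20% protein, and 9 without replicate 2 of 60% fat with 5% protein. Without replicate 2 of 20% fat with 1% protein 22 rose and 6 fell. With a surrogate variable 4 rose and camera's adjusted p was 0.245. The risers included Ddit4, which stands in 3 lists, Cebpb (0.90), Gpt2 (0.49), Pycr1 (0.48), Psat1 (0.42), an enzyme of serine synthesis, Asns (0.25), asparagine synthetase, and Atf4 (0.19), of which Atf4 did not pass in 17 of 26 alternatives and Asns and Pycr1 in 8 each. Nupr1 (-0.92), Slc7a11 (-0.89), a cystine transporter, Aldh1l2 (-0.64) and Hspa5 (-0.30) fell. The list's median was -0.0042 in replicate 2 of 20% fat with 1% protein against 5% protein at that fat level, and 0.19 in the contrast without that library.

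**Figure D4:**
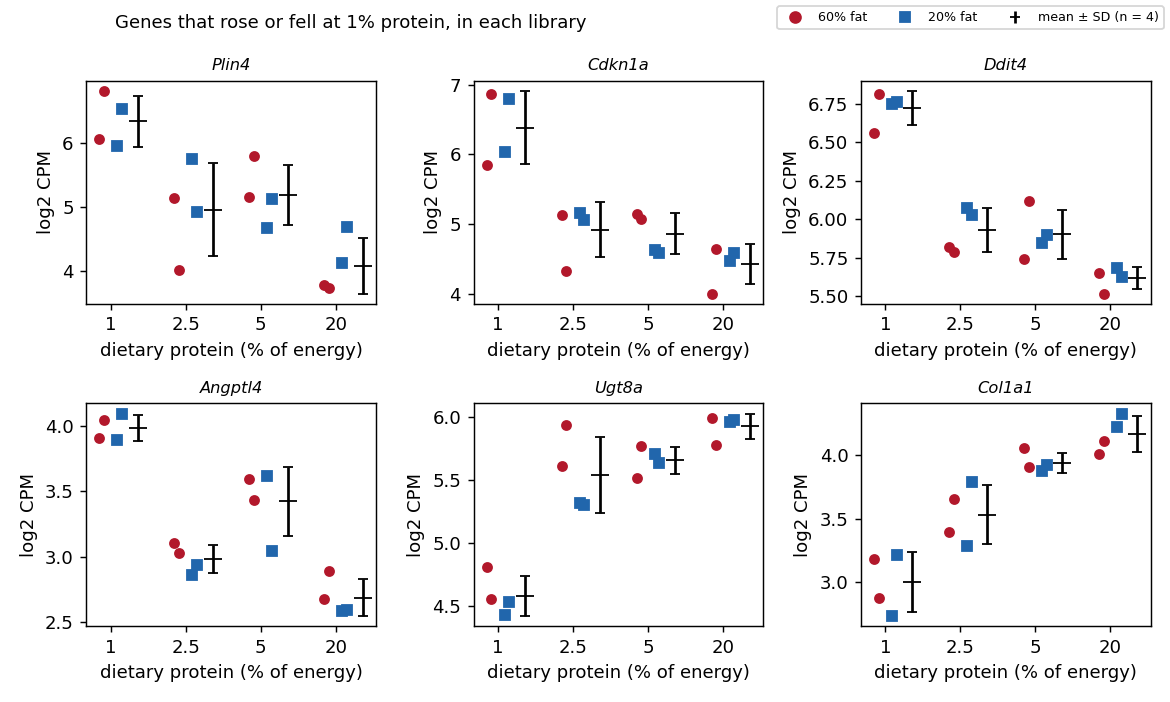
Each point is a library's log2 CPM of Plin4, Cdkn1a, Ddit4, Angptl4, Ugt8a or Col1a1 by dietary protein (% of energy), circles for 60% fat and squares for 20% fat, with black marks for the mean ± SD (n = 4). The first 4 genes lay above the range of the 20% protein libraries in all 4 libraries at 1% protein, and the last pair below it.

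Fuel metabolism genes went both ways at 1% protein: of 31 genes of fatty acid and ketone metabolism, 9 rose, 4 fell and 18 did not pass (adjusted over the list alone 10 rose and 4 fell, camera adjusted p = 0.153). Angptl4, an inhibitor of lipoprotein lipase, rose 2.49-fold (log2 1.31 ± 0.11 SE, adjusted p = 4.59e-06 in edgeR's quasi-likelihood test), Pdk4, which restrains pyruvate oxidation, by 0.87 and Cpt1a, of mitochondrial fatty acid uptake, by 0.20, though Cpt1a did not pass in 17 of 26 alternatives. Fabp7, a brain fatty acid binding protein (-1.53), Cd36 (-0.55), Scd1, a fatty acid desaturase (-0.54), and Elovl6 (-0.38) fell. Of 24 cholesterol synthesis genes, 8 fell, among them Idi1 (-0.46), Cyp51 (-0.30) and Hmgcs1 (-0.26), and 16 did not pass (adjusted over the list alone 8 fell, camera adjusted p = 0.0048 and adjusted p = 0.463 with an estimated correlation). Idi1 did not pass in 14 of 26 alternatives. The cholesterol list did not pass camera without replicate 2 of 20% fat with 1% protein (adjusted p = 0.141) or without the 2 libraries that carried cortex markers (0.145). Its 8 became 3 or 4 without either library of 60% fat with 1% or 20% protein or replicate 2 of 20% fat with 20% protein. Of 15 heat shock genes, 7 fell, such as Hspa1b (-0.72), Hspb1 (-0.58) and Hsph1 (-0.47), and 8 did not pass (adjusted over the list alone 10 fell, camera adjusted p = 6.09e-06 and adjusted p = 0.167 with an estimated correlation). The 7 became 2 to 4 without either library of 60% fat with 1% protein, replicate 1 of 20% fat with 1% protein or either library of 20% fat with 20% protein, and Hspa1b did not pass in 12 of 26 alternatives. In the clock list of 17 genes, Cry2 (0.38), Per1 (0.38), Cry1 (0.34), Hlf and Tef rose and 12 did not pass (adjusted over the list alone 6 rose, camera adjusted p = 0.0311 and adjusted p = 0.173 with an estimated correlation). The clock list did not pass camera without replicate 2 of 20% fat with 1% protein (adjusted p = 0.0816), replicate 2 of 60% fat with 1% protein (0.059), replicate 1 of 20% fat with 20% protein (0.0722) or the cortex-marker libraries (0.0704). Its 5 became 7, with 2 that fell, without that replicate 2 of 20% fat or without the cortex-marker libraries, 2 without that replicate 2 of 60% fat, and 3 without replicate 1 of 20% fat with 1% protein or replicate 2 of 20% fat with 20% protein. Of 27 autophagy and lysosome genes, Gabarapl1 (0.28) rose and Hexa (-0.22) fell (adjusted over the list alone 1 rose, camera adjusted p = 0.191).

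Genes of protein synthesis and of respiration shifted by small amounts. Of 74 ribosomal protein genes 38 rose and 36 did not pass (adjusted over the list alone 58 rose, median log2 0.25, camera adjusted p = 1.49e-18 and adjusted p = 0.372 with an estimated correlation), with Fau at 0.39 and Rplp0 at 0.38. Of 71 nuclear-encoded respiratory chain genes 23 rose, 1 fell and 47 did not pass (adjusted over the list alone 48 rose and 1 fell, median 0.20, camera adjusted p = 5.03e-12 and adjusted p = 0.445 with an estimated correlation), with Ndufv3 at 0.36, Ndufb9 at 0.33 and Ndufb2 at -0.22. Of 12 mitochondrially encoded genes mt-Nd2 (-0.52) fell and 11 did not pass (adjusted over the list alone none, median -0.34, camera adjusted p = 0.0048 and adjusted p = 0.508 with an estimated correlation), and mt-Nd2 did not pass in 11 of 26 alternatives. These lists moved with the libraries that stood apart. Against 5% protein at 20% fat, replicate 2 of 20% fat with 1% protein had medians of 0.06, 0.02 and 0.43, where the contrast without it had 0.31, 0.23 and -0.67. The ribosomal count was 55 without that library, 8 without replicate 1 of the same diet, 9 and 13 without replicates 1 and 2 of 60% fat with 1% protein, 9 without replicate 1 of 60% fat with 20% protein and 10 without replicate 2 of 20% fat with 20% protein. It was 22 with the length offset, 5 with only the libraries of the 2 levels fitted and 3 with a surrogate variable in the model. The respiratory chain count was 16 with the length offset, 1 with only the 2 levels or a surrogate variable, 37 with the replicate block and 48 without the cortex-marker libraries. It was 1 without replicate 1 of 20% fat with 1% protein or replicate 2 of 20% fat with 20% protein. It was 2 to 14 without any library of 60% fat or either of 20% fat with 2.5% protein, 36 without replicate 1 of 20% fat with 20% protein and 45 without replicate 2 of 20% fat with 1% protein.

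Vessel and connective tissue markers fell at 1% protein. Of 10 endothelial markers, 8 fell and 2 did not pass (adjusted over the list alone 8 fell, median log2 -0.45), such as Itm2a (-0.82), Cdh5 (-0.78), the cadherin of endothelial junctions, Abcb1a (-0.49) and Cldn5 (-0.46). The 8 became 3 without replicate 2 of 20% fat with 20% protein, and 4 without replicate 2 of 60% fat with 1% protein, replicate 2 of 60% fat with 20% protein or replicate 1 of 20% fat with 1% protein. A surrogate variable also left 4. Of 12 mural and fibroblast-like cell markers, 9 fell, 1 rose and 2 did not pass (adjusted over the list alone 9 fell and 1 rose, median -0.64). Lum (-1.24) and Dcn (-0.85), proteoglycans of the matrix, Col1a1 (-1.17, a collagen chain) and Rgs5 (-0.64, of pericytes) fell, and Kcnj8, a potassium channel of pericytes, rose by 0.65. Both lists passed camera (adjusted p = 1.81e-07 and 7.17e-09), with adjusted p = 0.166 for each with an estimated correlation. Their medians in replicate 2 of 20% fat with 1% protein against 5% protein at that fat level were -0.30 and -0.26, and -0.47 and -0.72 in the contrast without that library.

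Of 10 oligodendrocyte markers, Ugt8a, an enzyme of myelin lipid synthesis, was 2.55-fold lower (60.9 ± 4.09 to 24.0 ± 2.78 CPM, SD, n = 4 each; log2 -1.35 ± 0.11 SE, adjusted p = 3.51e-06 in edgeR's quasi-likelihood test). In all 3 fell, Ermn (-0.69) among them, and 7 did not pass (adjusted over the list alone 3 fell, camera adjusted p = 0.00247 and adjusted p = 0.372 with an estimated correlation). The oligodendrocyte list did not pass camera without replicate 2 of 20% fat with 1% protein (adjusted p = 0.124, median 0.0011, 2 rose and 3 fell) or without the cortex-marker libraries (0.122, median 0.0034, 3 rose and 3 fell). In that replicate 2 its median was -0.36 against 5% protein at 20% fat. Of 8 precursor markers, Enpp6 (-0.93) and Bmp4 (-0.82) fell (adjusted over the list alone 2 fell, median 0.0059 and mean -0.21, camera adjusted p = 0.13). Of 9 astrocyte markers Agt (0.58), Aldoc (0.36), Aldh1l1 (0.35) and Slc1a3 rose and Aqp4, the water channel of astrocyte endfeet, fell by 0.86 (adjusted over the list alone 5 rose and 2 fell, camera adjusted p = 0.246), and Slc1a3 did not pass in 16 of 26 alternatives. Of 12 microglia and macrophage markers Ctss (-0.33) fell (adjusted over the list alone 1 fell, 0.111), and of 14 tanycyte and ependymal markers Gpr50 (-0.60) fell (1 fell, 0.153). None of 8 neuron markers passed (adjusted over the list alone none; 0.52). Of 24 interferon response genes, 8 fell, such as Ifi44 (-1.69), Gbp2 (-1.06) and Oas1a (-0.93), and 16 did not pass (adjusted over the list alone 11 fell, camera adjusted p = 1.52e-05 and adjusted p = 0.31 with an estimated correlation). Oas1a did not pass in 18 of 25 alternatives, Ifi44 in 10 of 25 and Gbp2 in none. The 8 became 3 without either library of 60% fat with 1% protein or replicate 1 of 20% fat with 1% protein, 4 without replicate 2 of either diet with 20% protein and 5 without replicate 1 of 20% fat with 20% protein. Of 15 inflammatory genes Tlr4 (-1.12), Socs3, Tlr2 (-0.60) and Vcam1 (-0.57) fell and Lcn2 and Nfkbia (0.86) rose (adjusted over the list alone 2 rose and 6 fell, median -0.17 and mean -0.017, camera adjusted p = 0.111). Lcn2 and Nfkbia also stand in the glucocorticoid response list. Tlr4 was low in 3 of the 4 libraries at 1% protein (log2 CPM -1.162 to -0.574). In replicate 2 of 20% fat it stood at 0.926, within the 0.443 to 1.069 at 20% protein.

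Of 14 thyroid axis genes, Hr, a thyroid hormone target (1.17), and Thra (0.28) rose and 3 fell, among them Trhr (-0.87) and Slco1c1 (-0.51), a thyroid hormone transporter (adjusted over the list alone 2 rose and 3 fell, camera adjusted p = 0.612). Of 19 growth hormone and IGF genes Sst (0.48), somatostatin, rose and Sstr1 (-0.32), Igfbp5 (-0.21) and Igf2r (-0.19) fell (2 rose and 5 fell adjusted over the list alone, 0.246). Of 10 reproductive axis genes, 3 fell, among them Greb1 (-0.57) and Tacr3 (-0.41) (5 fell adjusted over the list alone, camera adjusted p = 0.0173 and adjusted p = 0.343 with an estimated correlation). The reproductive list's mean log2 relative to all libraries was -0.208, -0.18 and -0.167 in the 3 libraries at 1% protein with the lowest mitochondrial share and -0.019 in the 4th. The 4th had a median of 0.04 against 5% protein at 20% fat, where the contrast without it had -0.41. Of 22 GABA and glutamate genes, Gad2 (-0.34) and Gabra3 (-0.20) fell, 1 rose and 19 did not pass (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0187 and adjusted p = 0.508 with an estimated correlation). Like the reproductive list, the GABA and glutamate list moved with the libraries that stood apart. Its mean log2 relative to all libraries was -0.395, -0.247 and -0.208 in the 3 libraries at 1% protein with the lowest mitochondrial share and 0.262 in the 4th, whose median against 5% protein at 20% fat was 0.20, where the contrast without it had -0.37. Among 21 immediate early genes Dusp1 (0.33) rose and Jun (-0.17) fell (none adjusted over the list alone, camera adjusted p = 0.724), and each did not pass in 14 of 26 alternatives.

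Marker lists of hypothalamic nuclei did not pass camera. In the arcuate list of 11 genes Npy, Agrp and Sst rose and Pomc and Isl1 (-0.37) fell (adjusted over the list alone 3 rose and 2 fell and adjusted p = 0.99). In the paraventricular and supraoptic list of 10, Nptx2 (0.45) and Crh rose and Sim1 (-0.67) and Avp fell (2 rose and 3 fell adjusted over the list alone, 0.666), and Nptx2 and Sim1 did not pass in 12 of 26 alternatives each. In the lateral hypothalamic list of 10, Qrfp and Nptx2 rose and Cartpt, Tacr3 and Rfx4 fell (3 rose and 3 fell adjusted over the list alone; 0.993; the median of 0.13 is positive and the test's direction downward). The ventromedial (Gpr149, -0.33; 0.111), suprachiasmatic (Avp; 0.253) and mammillary lists (Sim1 and Nos1, -0.28; 0.52) had 1, 1 and 2 genes that fell of 9, 12 and 10 (adjusted over the list alone 1, none, and 2 with 1 rising). Neighbouring tissues were measured too. Of 13 thalamic markers 6 rose and 7 did not pass, among them Prkcd (1.06), Gbx2 (0.86), Synpo2 (0.81) and Ramp3 (9 rose adjusted over the list alone, camera adjusted p = 0.000461 and adjusted p = 0.455 with an estimated correlation). The 6 became 1 without replicate 2 of 60% fat with 1% protein, replicate 2 of 60% fat with 20% protein or replicate 1 of 20% fat with 1% protein, and 0 with a surrogate variable. Ttr, the main transcript of choroid plexus, rose by log2 3.26 (adjusted p = 0.0297 in edgeR's quasi-likelihood test). It averaged 85.8 ± 89.5 against 8.08 ± 4.74 CPM (SD, n = 4 each), with 3 of 4 libraries at 1% above all at 20%. It did not pass in 5 of 26 alternatives, over which its log2 change ran from 2.385 to 4.215. Its highest counts, 3879 and 3240, were in the libraries with cortex markers, at 1% and 2.5% protein. The other libraries at 1% protein had 228, 537 and 1600. Ttr was the single choroid marker of 11 that passed (1 rose adjusted over the list alone, camera adjusted p = 0.224). Syndig1l (0.42) rose of 14 striatal markers (1 rose adjusted over the list alone, 0.29), and Slc18a2 fell of 8 monoamine neuron markers (1 fell, 0.18). None of 14 cortical (0.444), 8 pituitary (0.567) or 5 red blood cell markers (0.808) passed over all genes or adjusted over the list alone.

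In all, 2376 genes passed between 1% and 20% protein, 1375 higher and 1001 lower, with 5273 at an unadjusted p under 0.05 and 154 changed at least 2-fold. The largest changes are ranked here among genes with a proper symbol and a mean of at least 1 CPM. Beside Ttr, Plin4, Npy and Cdkn1a, the highest changes were those of Otoa (2.99), Itgad (2.26), Pla2g3 (1.92), Klrg2 (1.84), Wfikkn2 (1.71) and Ccl17 (1.57), a chemokine. Beside Pomc, the lowest were Slc47a1 (-1.92), an organic cation transporter, H2-Aa (-1.91), H2-Ab1 (-1.88) and H2-Q1 (-1.55), of antigen presentation, Thbd (-1.68), thrombomodulin of vessel walls, Slc26a7 (-1.62), Fam180a (-1.59), Akr1c14 (-1.59) and Cdh1 (-1.56), E-cadherin. Of the genes named for this contrast, Gabra3 did not pass in 9 of 26 alternatives, Igf2r, Rps6, Syndig1l and Tlr4 in 8, and Maf1, Ndufb9, Oprm1, Tacr3, Thra and Slc26a7 in 7. Gabarapl1, Hexa, Nr3c1, Rfx4 and Sst did not pass in 6, and Atg13, Cldn5, Isl1, Ndufb2, Nos1 and Tlr2 in 5. Of the 44 lists, 16 passed camera, none with an estimated correlation, and 19 passed fry. With only the libraries of the 2 levels fitted, 1 mTOR, 4 ATF4 and 3 clock genes rose, and 2 interferon, 2 heat shock and 3 cholesterol genes fell. A surrogate variable left 3 clock genes that rose and 4 interferon genes that fell, with 6 oligodendrocyte genes that fell. The length offset left 5 endothelial genes that fell, and no filter left 4 mTOR genes that rose and 5 cholesterol genes that fell. The count was 1198 with a surrogate variable in the model, 806 with only the libraries of the 2 levels fitted and 5889 without the 2 libraries that carried cortex markers. It was 5616 without replicate 2 of 20% fat with 1% protein and 939 without replicate 1 of that diet. The others that moved it by over 1.5 times gave 1135 and 978 without replicates 1 and 2 of 60% fat with 1% protein, 1083 and 1355 without replicates 1 and 2 of 60% fat with 20% protein, and 961 without replicate 2 of 20% fat with 20% protein.

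**Figure D5:**
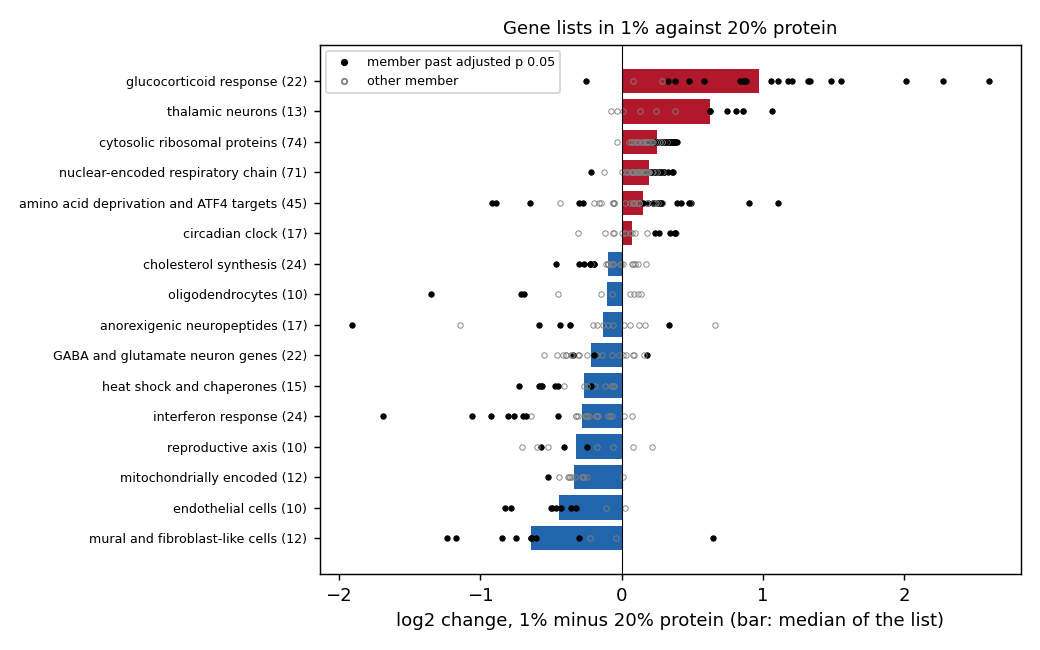
Bars give the median log2 change from 20% to 1% protein of each list that passed camera at the preset correlation, with the number of measured genes in parentheses; points are its genes, filled where past an adjusted p of 0.05. Glucocorticoid response genes had the highest median (0.97) and mural and fibroblast-like cell markers the lowest (-0.64), and none of the 16 lists passed with an estimated correlation.

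The intermediate protein levels asked whether a change appears before the lowest level. At 5% against 20% protein Angptl4 rose by log2 0.76 ± 0.11 (SE), Mt2 by 0.61 ± 0.08 and Mt1 by 0.42 ± 0.07, and Ednrb, an endothelin receptor, fell by 0.34 (adjusted p = 0.0181, 0.00749, 0.0369 and 0.0177 in edgeR's quasi-likelihood test). None of these genes passed at 2.5% against 20% protein, where each lay on average nearer to 20% protein than at 5%. Angptl4 had log2 CPM of 3.041 to 3.617 at 5%, 2.861 to 3.106 at 2.5% and 2.585 to 2.887 at 20%. Ednrb had 6.117 to 6.263, 6.171 to 6.372 and 6.452 to 6.609. Their changes thus did not grow steadily as protein fell. The 5th gene called, Rnf181, had 66 and 62 counts in the libraries of 20% fat with 20% protein and 0 or 1 in all others. It was chosen after its values were seen, and it was the single gene called at 2.5% against 20% protein, where 801 had an unadjusted p under 0.05. At 5% against 20%, 501 had, and of 26 alternatives Angptl4 failed to pass in 7, Mt1 in 14, Ednrb in 8 and Mt2 in 0. Npy stood at 0.82 at 2.5% against 20% protein (adjusted p = 0.328), Pomc at -0.93 (0.12) and Col1a1 at -0.63 (0.12). Glucocorticoid response genes had medians of 0.29 at 5% (2 of 22 rose, 6 rose adjusted over the list alone and adjusted p = 0.265 with an estimated correlation) and 0.20 at 2.5% (4 rose adjusted over the list alone, 0.179). Mural and fibroblast-like cell markers had -0.34 at 2.5% against 20% protein (7 of 12 fell adjusted over the list alone), and this was the only list of 44 in these contrasts past the threshold with an estimated correlation (adjusted p = 0.0392). At 5% against 20% the count was 1 to 3 without any single library of those 4 diets: 2 and 2 without those of 60% fat with 5% protein, 2 and 3 for 60% fat with 20%, 1 and 3 for 20% fat with 5%, and 1 and 1 for 20% fat with 20% protein. The count at 2.5% against 20% was 26 with DESeq2, 36 with the likelihood ratio test, 29 with a surrogate variable and 50 without the cortex-marker libraries. It was 17 without replicate 2 of 20% fat with 1% protein and 3 without replicate 2 of 60% fat with 2.5% protein. It was 2 without replicate 1 of 60% fat with 1% protein, replicate 1 of 60% fat with 2.5% protein, either library of 60% fat with 5% protein or replicate 2 of 20% fat with 2.5% protein, and 0 without replicate 1 of 20% fat with 2.5% protein or either library of 20% fat with 20% protein.

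Between 1% and 2.5% protein, whose diets share the start of their codes, 386 genes passed, 231 higher and 155 lower (3681 unadjusted). Npy rose by log2 1.35 (adjusted p = 0.0015) and Ddit4 by 0.79 (1e-04), and Pomc changed by -0.98 (0.015; edgeR's quasi-likelihood test). Among genes with a proper symbol and a mean of at least 1 CPM, the largest changes were those of Itgad (1.87), Otoa (1.78), Wfikkn2 (1.54), Cdkn1a (1.5) and Pla2g3 (1.37) upward and of Fabp7 (-1.29), H2-Ab1 (-1.15), Fbxw15 (-0.99), Pomc and Ugt8a (-0.97) downward. Of 26 alternatives H2-Ab1 did not pass in 7, Otoa in 5 and Pomc in 3. Of the glucocorticoid response genes 13 of 22 rose and 1 fell (18 rose and 1 fell adjusted over the list alone, median 0.77 and adjusted p = 0.155 with an estimated correlation). Of the endothelial markers 1 of 10 fell (7 fell adjusted over the list alone, median -0.35 and adjusted p = 0.355 with an estimated correlation). Ribosomal protein genes had 4 of 74 that rose (29 rose adjusted over the list alone, median 0.17 and adjusted p = 0.502 with an estimated correlation). The count was 705 with DESeq2, 789 with the likelihood ratio test and 53 with only those 8 libraries fitted. It was 4265 without replicate 2 of 20% fat with 1% protein and 145 without replicate 1 of it. It was 189 and 106 without replicates 1 and 2 of 60% fat with 1% protein, 159 and 95 without those of 60% fat with 2.5% protein, and 253 without replicate 2 of 20% fat with 2.5% protein.

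At each fat level, 2 libraries at 1% protein were set against 2 at 20%. The leading genes are given among those with a proper symbol and a mean of at least 1 CPM. At 60% fat 707 genes passed (328 higher, 379 lower and 4692 unadjusted). Plin4 (log2 2.74), Itgad (2.28), Otoa (2.28), Cdkn1a (2.1) and Klrg2 (1.78) led upward, and H2-Ab1 (-1.96), Cdh1 (-1.93), Thbd (-1.90), Prg4 (-1.84) and Pomc (-1.81) downward. Of 26 alternatives Otoa did not pass in 12, Prg4 in 11, H2-Ab1, Cdh1 and Thbd in 5 each, and the other 5 in 0 to 3, and Prg4 ran from -2.27 to -0.63 over the 26. At 20% fat 297 passed (100 higher, 197 lower and 2568 unadjusted). Otoa (3.70), Npy (2.66), Itgad (2.26), Pla2g3 (2.12) and Wfikkn2 (1.99) led upward, and H2-Aa (-2.48), Pomc (-1.99), Cd74 (-1.98), Akr1c14 (-1.90) and H2-Ab1 (-1.81) downward, and each of these 10 did not pass in 0 to 4 of 26 alternatives. Npy rose by 1.66 at 60% fat, and its difference between fat levels was -1.01 ± 0.32 (SE and adjusted p = 0.623 in edgeR's quasi-likelihood test). No gene passed the test of that difference (1305 unadjusted; DESeq2 0, likelihood ratio test 3). The 2 contrasts share no library: 144 genes were called in both, all in the same direction, where 12.6 would be shared by independent lists (68 higher in both against 1.97, 76 lower against 4.49). They do share an estimate of each gene's spread, so the same genes are easier to call in both. The 12.6 is thus not a fair chance level. Of the libraries at 1% protein, 3 across both fat levels also share a low mitochondrial share and lower long genes. The overlap is therefore no independent replication of a diet effect. The count at 60% fat was 106 with a surrogate variable and 2131 without a filter, and leaving out 1 library gave 16 to 84 for its own 4 libraries, replicate 2 at 1% protein lowest. Leaving out either library of 20% fat with 1% protein gave 2747 and 2748, of 20% fat with 5% protein 1386 and 1393, of 20% fat with 20% protein 313 and 311, of 60% fat with 2.5% protein 292 and 291, and of 60% fat with 5% protein 243 and 249. The count at 20% fat was 805 without replicate 2 of 1% protein and 80 and 53 without the replicates of 20% protein.

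The protein slope taken at each fat level, and its difference, called few genes. At 60% fat edgeR's quasi-likelihood test called 0 (1090 unadjusted; DESeq2 3, likelihood ratio test 1), at 20% fat it called Rnf181 alone (1431 unadjusted; DESeq2 14, likelihood ratio test 26), and the interaction of protein with fat called 0 (472 unadjusted; DESeq2 0, likelihood ratio test 0). Across genes, which are not independent replicates, the slopes at the 2 fat levels correlated with r = 0.335 and rho = 0.386 (permutation p = 0.0456, all 2520 arrangements at 60% fat, two-sided), and 65.8% of genes had the same sign. The p lay above 0.05 with a 1 CPM filter (permutation p = 0.0552), with the length offset (0.052) and when any of the 8 libraries at 60% fat (0.054 to 0.214) or replicate 1 of 20% fat with 1% protein (0.0937) was left out, and at 0.05 without replicate 1 of 20% fat with 2.5% protein. Pearson correlations with protein passed adjustment for no gene at either fat level (exact permutation test; smallest adjusted p 0.44 and 0.236, smallest possible p 0.000397). Of 16646 genes, 1241 (7.46%) had an unadjusted p under 0.05 at 60% fat and 1130 (6.79%) at 20% fat. Npy had r = -0.68 (exact permutation p = 0.0393) and rho = -0.83 at 60% fat and r = -0.75 (exact permutation p = 0.0361) and rho = -0.98 at 20% fat. Without the 20% protein libraries r was -0.83 (exact permutation p = 0.1) and -0.88 (0.0444). Pomc had r = 0.63 (exact permutation p = 0.0365) and 0.80 (0.00357), with rho = 0.93 at both, and 0.84 and 0.97 without 20% protein. Agrp had r = -0.84 (exact permutation p = 7.94e-04) at 60% fat and -0.49 (0.205) at 20% fat.

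For dietary fat, the question was which genes differ between 60% and 20% of energy as fat, 8 libraries against 8. No gene passed edgeR's quasi-likelihood test (1066 unadjusted; DESeq2 0, likelihood ratio test 0; smallest adjusted p 0.674). Npy had log2 -0.42 (60% minus 20% fat and adjusted p = 0.727), Pomc 0.15 (0.859), Agrp -0.01 (0.971), Cartpt 0.16 (0.727), Hcrt 0.12 (0.78), Pmch 0.03 (0.94) and Mtor 0.04 (0.772). Of 44 lists 13 passed camera, and none did with an estimated correlation (adjusted p = 0.121 to 0.791) or in fry. Medians were positive for thalamic (0.24), microglia (0.10), oligodendrocyte (0.10), astrocyte (0.06), heat shock (0.06), respiratory chain (0.05), autophagy (0.05), ATF4 (0.05), fatty acid (0.04) and ribosomal lists (0.04), and negative for cortical (-0.31), choroid plexus (-0.27) and endothelial lists (-0.10). No member passed over all genes, and adjusted over the list alone 2 astrocyte genes rose and no other did. Of the 2 libraries that carried cortex markers, both were at 20% fat.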

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

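The tests of gene length, diet code, RNA makeup, arcuate tissue and pituitary tissue, with their limits, were chosen after the results were seen, while the counts over other splits of the samples were set beforehand.

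Of 52 groups, made of 13 measures at 4 protein levels, 6 held a library far from the other 3, and chance flags about 1 in 20 groups. At 1% protein, replicate 2 of 20% fat stood apart in 3 measures. Mitochondrial genes held 3.20% of its counts (the others 1.54% to 1.78%), the top 10 genes held 3.98% (3.31% to 3.35%), and its cortex and hippocampus marker score was 0.71 (-0.26 to -0.23). At 2.5% protein, Npy stood at 44.3 CPM in replicate 2 of 20% fat (25.4 to 28.5 in the others), and Mtor at 168 CPM in replicate 1 of 20% fat (161 to 162). That Npy value came from a library with cortex markers. At 5% protein, replicate 2 of 20% fat had a total of 17730000 counts, rounded, against 18360000 to 18430000.

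The breadth of the change between 1% and 20% protein, 2376 genes, was weighed against 3 explanations. A trend with gene length is argued against as the whole cause, because 2291 genes were called with the trend removed, and 1952 of them (82.2% of the 2376) were shared. The start of the diet code, which separates 1% and 2.5% from 5% and 20% protein, is argued against by the single call (1) between 2.5% and 20% protein. The RNA makeup that 3 of the 4 libraries at 1% protein share may account for much of the breadth: of 5597 genes called without replicate 2 of 20% fat with 1% protein, 43.3% lay the same way in that library against 5% protein at 20% fat, where chance gives 50%, and 36.3% against 2.5% protein, though 67.2% of the 271 that changed by over log2 1 did. This stays open, since that library also carried cortex markers and could itself be the odd sample, and an effect of the diet on these genes stays open with it. The 5597 genes are also another set than the 2376, which were called with that library in the fit. The share of the 2376 that lay the same way was not measured.

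Higher Npy, Agrp and glucocorticoid response genes and lower Pomc formed the pattern seen in all 4 libraries at 1% protein against those at 20%. Npy had 1013 to 2206 counts against 254 to 815 in all other libraries, and Pomc 204 to 248 against 317 to 1080. Agrp did not separate from the middle levels: its lowest was 5.92 CPM at 1%, against highest values of 6.39 at 2.5% and 6.08 at 5%. The 2206 and 815 counts of Npy were in the libraries with cortex markers, without which Npy still rose by log2 1.97. An equal loss of all arcuate tissue from the piece is argued against, since Agrp changed by log2 0.59 while Pomc changed by -1.91. This rests on Agrp, whose 72 to 154 counts per library came from a span that overlaps 2 coding genes. A cut that took unequal parts of the nucleus was not tested. Pituitary tissue that carries Gh and Prl is argued against as the main source of Pomc's loss. Gh and Prl together lost 56.8 counts on average from 20% to 1% protein, 8.71% of Pomc's loss of 652. Pituitary cells that make Pomc without Gh or Prl are not covered by this test. Removing the gene length trend left the glucocorticoid median at 0.92 (0.97 before). A response of these genes to the diet is thus a hypothesis that these tests leave standing, found and tested on the same libraries, and food intake and hormone levels were not measured here.

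Lower vessel and fibroblast-like cell markers at 1% protein were set against the diet code and gene length. For the endothelial list the diet code is argued against as the whole cause, as the median was -0.35 between 1% and 2.5% protein, which share a code start, and -0.10 between 2.5% and 20%. The -0.10 leans on replicate 2 of 20% fat with 2.5% protein, which carried cortex markers. Its mean log2 of the list relative to all libraries was 0.285, against -0.099 to -0.042 in the others at 2.5%. Libraries at 20% protein had 0.002 to 0.237, so a part that follows the code stays open. For the mural and fibroblast-like list it cannot be told apart from protein, since the median was -0.34 between 2.5% and 20% protein and -0.17 between 1% and 2.5%. The length trend is argued against for both, with medians of -0.41 and -0.61 after its removal. Whether the piece held fewer vessels and less meningeal tissue, or these cells expressed less, stays open and may differ between libraries.

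Other splits of the samples bear on each count of calls. Of 12 results tested so, only 5% against 20% protein had a count met by under 5% of the splits. Its real 5 genes were met by 1 of 35 splits, the real one and the smallest share that 35 splits allow, and the highest other split called 2. No adjustment was made for testing 12 results, so chance is not excluded for this contrast either. The margin is narrow: leaving out any of those 8 libraries left 1 to 3 genes, and Rnf181, 1 of the 5, had more than 1 count only in the libraries of a single diet. Chance cannot be excluded for 1% against 20% protein: 3 of 35 splits called as many as the real 2376, and the highest other called 3589 by grouping 3 of the 1% protein libraries with replicate 1 of 20% fat with 20% protein. Nor can it for 1% against 2.5% protein (3 of 35; real 386, highest other 3005, with the same 3 libraries together), 2.5% against 20% (6 of 35; real 1, highest other 1) or the 16 lists of 1% against 20% (6 of 35; highest other 22). Chance cannot be excluded for the protein slope either (5 of 60 drawn; real 3, highest other 1050), its value at 20% fat (20 of 60; 1 and 144) or its lists (29 of 60; 13 and 20). The same holds for the lists of the fat effect (20 of 60; 13 and 22). A real count of 0 is met by all 60 splits by construction, so nothing was tested for the slope at 60% fat (highest other 2574), the interaction (14) and the fat effect (1). The split that called 1050 and 2574 put both 1% protein libraries of 60% fat at 20% and both 20% protein libraries of 60% fat at 1%, which is that diet grouping turned round, so its excess does not tell a structure of the samples from a step at 1% protein. The split with 3005 also kept 3 of the 4 libraries at 1% protein together. The split with 144, many times the real 1, put both libraries with cortex markers at 20% protein. It also moved other libraries, and whether the cortex markers caused its calls was not tested.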

How the results depend on the processing

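The removal of a gene length trend, the fits without the 2 libraries with cortex markers, the list tests of 1% against 20% protein and the difference between fat levels were chosen after seeing the data. Of 168 pairs of a named gene and a comparison, the alternatives that kept the libraries or dropped several gave 1532 values with the same direction and side of the threshold, 149 weaker, 10 stronger and 16 reversed. Leaving out a library gave 2190, 480, 1 and 17. For 1% against 20% protein the count stayed between 2107 and 2786 with other scalings, tests, filters, the replicate block and the length offset, and became 1198 with a surrogate variable, 5889 without the cortex-marker libraries and 806 with only the 2 levels. Npy kept log2 1.97 to 2.42 and Pomc -2.06 to -1.76 in every alternative run for that contrast. With DESeq2 the counts were 82 for the protein slope, 3 and 14 for the slopes at 60% and 20% fat, 26 for 2.5% against 20%, 705 for 1% against 2.5% and 1319 for 1% against 20% at 60% fat. With the likelihood ratio test they were 100, 1, 26, 36, 789 and 1880 in that order, 546 at 20% fat and 3 for the difference between fat levels. Without a filter they were 8 for the slope, 1 for the interaction, 25 for 2.5% against 20%, 2131 and 560 for 1% against 20% at 60% and 20% fat and 1 for the difference. A surrogate variable gave 3 for the slope at 20% fat, 29 for 2.5% against 20%, 106 and 940 for 1% against 20% at 60% and 20% fat and 8 lists for the fat effect. On a log2 protein scale the slope called 1311 and the slope at 20% fat 144. The diet code term gave 0 for the slope. Without 20% protein the slope called 24 and the slope at 20% fat 0. Without the cortex-marker libraries the counts were 1 for the slope, 4 for the slope at 20% fat, 50 for 2.5% against 20%, 4026 for 1% against 2.5%, and 2865 and 927 for 1% against 20% at 60% and 20% fat. With fewer libraries fitted they were 1 for the slope at 60% fat, 5 for 2.5% and 3 for 5% against 20%, 53 for 1% against 2.5%, and 3369 and 26 for 1% against 20% at 60% and 20% fat. Dropping the interaction for every gene gave 1 for the fat effect. An estimated correlation left 0 lists for the slope, the fat effect and 1% against 20%, and fry called 5, 0 and 19. Pearson correlations had 1241 and 1130 genes at an unadjusted p under 0.05 at 60% and 20% fat. The similarity of slopes was 0.394 with a 1 CPM filter (permutation p = 0.0552) and 0.324 with the length offset (permutation p = 0.052). The cause of these shifts was not tested, beyond the smaller number of libraries where libraries were dropped.

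The replicate numbers showed no general pairing of the samples: over 28 pairs of diets the correlation of deviations ran from -0.17 to 0.339, median 0.02, with 7 above 0.1. A batch that follows the replicate number in some of the diets stays open, since the block raised several counts. With the replicate block the counts were 7 for 2.5% against 20%, 1858 for 1% against 20% at 60% fat, 2786 for 1% against 20%, 572 for 1% against 2.5% and 365 for 1% against 20% at 20% fat, and within 1.5 times the reported count for the others.

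Leaving out a library gave 0 to 10 genes for the slope, 0 to 3 and 1 to 3 for the slopes at 60% and 20% fat, 0 to 1 for the interaction and for the fat effect, 939 to 5616 for 1% against 20%, 0 to 17 for 2.5% and 1 to 5 for 5% against 20%, 95 to 4265 for 1% against 2.5%, 16 to 2748 and 53 to 805 for 1% against 20% at 60% and 20% fat, and 0.191 to 0.344 for the similarity of slopes. The highest values for 1% against 20% and against 2.5% were those without replicate 2 of 20% fat with 1% protein. A diet left with 1 library was assumed to vary like the others.

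Values that changed sign lay near 0. For Pmch, protein slope values were -0.184 with the diet code term and -0.00769 with the length offset. For Mtor, protein slope values were 0.00866 on the log2 protein scale, 0.0328 with the diet code term, 0.0430 with the length offset, 0.00982 without the cortex-marker libraries and -0.0224 to 0.00663 leaving out a library. A surrogate variable gave -0.0030 for Hcrt, 1% against 20% protein, and -0.0366 for Mtor, 1% against 20% protein. For Pmch, 1% against 20% protein gave -0.0848 with a surrogate variable, -0.00436 with median-ratio scaling and with DESeq2, -0.00478 without a filter, -0.00166 with a 1 CPM filter, -0.00475 with the replicate block, -0.135 with the length offset, -0.0120 with only the 2 levels and -0.0956 to 0.0478 leaving out a library. Agrp had 72 to 154 counts per library, so counting error weighs more on it than on Npy, with 254 to 2206.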

Other observations

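The genes and tests in this part were chosen after their values were seen. Single genes outside the lists, picked by their values and not tested as a group, were lower at 1% than at 20% protein. Slc22a8, an organic anion transporter of brain barriers, averaged 11.6 ± 2.12 against 24.8 ± 1.57 CPM (SD, n = 4 each; log2 -1.10 ± 0.14 SE), Aldh1a2, which makes retinoic acid, had log2 -1.13 ± 0.23, Foxc1, a transcription factor of the developing meninges, -0.68 ± 0.10, Slc13a4, a sulfate transporter, -0.99 ± 0.25 and Crabp2, a retinoic acid binding protein, -0.94 ± 0.23 (adjusted p = 0.000211, 0.00479, 0.000834, 0.0184 and 0.0171 in edgeR's quasi-likelihood test). Cd74, the invariant chain of class II antigen presentation, averaged 3.67 ± 0.818 against 10.6 ± 2.24 CPM (log2 -1.53 ± 0.23, adjusted p = 0.00077), beside H2-Aa and H2-Ab1. At 5% protein Slc22a8 averaged 23.4 CPM and Cd74 8.41.

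Some genes outside the lists rose. Fbln5, an elastic fibre protein, averaged 65.7 ± 8.25 CPM at 1% protein, 28.5 at 2.5%, 31.8 at 5% and 26.3 ± 2.82 at 20% (SD, n = 4 each; log2 1.32 ± 0.10 SE). Cebpd and Rasd1, both known as glucocorticoid-induced genes, had log2 1.25 ± 0.15 and 1.07 ± 0.13. The adjusted p values were 1.38e-06, 0.00015 and 0.000178 in edgeR's quasi-likelihood test. Ednrb fell by 0.65 at 1% protein (2.23e-06), and it had also passed at 5%.

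Ppp1ca was nearly absent from some libraries and present in others, in diets that differed in fat and protein: it had 119 and 103 counts in the libraries of 60% fat with 20% protein, 104 in replicate 1 of 20% fat with 2.5% protein and 118 in replicate 1 of 20% fat with 5% protein, and 0 to 2 elsewhere. Rnf181 followed a single diet, with 66 and 62 counts in the libraries of 20% fat with 20% protein and 0 or 1 elsewhere.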
